A study of Rattus norvegicus with 120 samples.

How the data were processed

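Testis RNA of male Wistar rats was measured on 120 one-colour arrays, with 4 animals in each of 30 groups. The groups were 10 at each of 3 ages: untreated controls (CTRL), and flutamide (FLUT), prochloraz (PROC) and vinclozolin (VINC) at 3 doses each. Per the labels' protocols, total RNA was taken from frozen powdered testis, labelled with Cy3 by an Agilent amplification kit and hybridised to Agilent arrays. The values deposited by the authors are log2 intensities, 62976 features by 120 arrays, and the submitters' processing notes name limma with no version given. The scanner, the background correction and any spot filter are not given in the sources used here. From the values, the 40 arrays of PND21 shared 1 distribution with a lowest log2 value of 6.02, and the arrays of PND30-40 and PND83 shared another with a lowest value of 4.59, so that the deposited log2 values appear as 2 separately quantile-normalised sets. Medians per array lay between 8.31 and 8.32 log2 at PND21, between 8.585 and 8.587 at PND30-40, and between 8.58 and 8.59 at PND83. No value column was left unused.

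Array features were listed by number alone and were not paired with probe or gene names in the tables used here. Counts are therefore of array features, which can include control spots and repeated probes. The 15 gene lists fixed before the data were examined, the sentinel genes and the cell type markers could not be applied, and the set tests on them were not run. The rule for named genes (the largest rises and falls at the LOAEL among features with an adjusted p under 0.05 whose 4 treated arrays all lay on the same side of the control mean) was kept, with 2 features named in each direction over the 9 LOAEL comparisons.

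Within an age, values were used as deposited. Comparisons across ages used values quantile-normalised again over the arrays in the fit (limma), which cannot separate the age of PND21 from its own deposited normalisation. A feature was tested if it lay above the 30th percentile of the array on at least 4 arrays in the fit, which left 49134 features at PND21, 46441 at PND30-40, 46017 at PND83, 46664 among controls and 53445 over all arrays. Linear models with 1 coefficient per group and moderated statistics were fitted in limma 3.58.1 under R 4.3.3, with 30 residual degrees of freedom within each age, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A feature with an adjusted p under 0.05 is named as called. The 41 comparisons were 27 of a treated group with controls of its age, 9 between compounds at the LOAEL, 2 between control ages, and 3 moderated F tests of whether the response at the LOAEL differed between ages. The 41 comparisons and the groups of animals were fixed before the data were examined.

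The labels give separate animals but not their litters. Dams were dosed during gestation and lactation, and the p-values measure the spread between animals as sampled. If animals of a group were littermates, that spread leaves out differences between litters, and the p-values would be too small. No pair of arrays had most of its values identical, and no duplicate was found. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.0978 at PND21, 0.14 at PND30-40 and 0.085 at PND83. The models were tested on simulated data built from the real feature means and spreads, with known changes in FLUT at the LOAEL. Of features changed by 0.5 log2, 67.2% were recovered at PND21 among 49134 features, 26.9% at PND30-40 among 46441 and 62.7% at PND83 among 46017. Of those changed by 1 log2, 98.5%, 85.1% and 100% were recovered. Simulated deviations were independent between arrays and between features. The shares recovered may therefore not hold for real arrays that deviate together.

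A maturation index was computed for each array by projection on the line from the mean of PND21 controls (0) to the mean of PND83 controls (1). Maturation feature groups for a compound were the features that differed at least 2-fold between neighbouring ages in the treated arrays of the other 2 compounds, so that no array entered both sides. They were tested with camera in limma at its preset inter-feature correlation and again with an estimated one. Index and groups were chosen after the data were seen.

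Other settings, chosen before the data were examined, were centring on the 75th percentile, no filter, a 50th percentile filter, only the 2 groups compared, limma array weights, the last digit of the sample number as a replicate block, a 1.5-fold minimum and leaving out each array in turn. Removal of the local mean over 11 by 11 features on each array, the maturation index as a covariate, and leaving out doubted arrays, those farthest out on the leading components of the within-group deviations, were added after the data were seen. The index is itself computed from the array values it then adjusts. The mean of all probes of a gene, normexp correction and slide as a block could not be run, since probe names, scanner values and slides are not in the sources used here.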

Results

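Testes of male rats exposed to 3 antiandrogenic compounds, through their dams and then directly, were profiled at weaning (PND21), at the time of sexual maturation (PND30-40) and in early adulthood (PND83). Flutamide is a drug that blocks the androgen receptor, vinclozolin a fungicide whose metabolites block it, and prochloraz a fungicide that blocks it and also inhibits steroid synthesis. Doses in mg/kg per day were 0.0025, 0.25 and 2.5 of flutamide, 0.01, 5 and 30 of prochloraz, and 0.005, 4 and 20 of vinclozolin, named ADI, NOAEL and LOAEL in rising order. Each of the 30 groups held 4 animals. Correlations between arrays of an age were at least 0.982 across features. Array features had no gene names in the tables used here, so the changes are given as numbers of features and as groups of features defined by their change with age.

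The control testis changed most between PND21 and PND30-40. Of 46664 features, 14548 were higher and 24456 lower at PND30-40 than at PND21 (limma, n = 4 per age), and 23557 of these differed at least 2-fold. The median size among called features was 1.20 log2. The PND21 arrays had been normalised separately from the others, so this comparison also holds any difference between the normalisations. Between PND30-40 and PND83, 7414 features were higher and 8136 lower at PND83, with a median size of 0.50 log2, and 1328 differed at least 2-fold.

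At PND21, testes of animals given prochloraz or vinclozolin had more features called lower than higher against controls, and those given flutamide had few called features. Prochloraz at the ADI had 191 features higher and 1298 lower, at the NOAEL 156 and 1349, and at the LOAEL 106 and 949 (limma, 4 animals per group). Vinclozolin at the ADI had 157 higher and 389 lower, at the NOAEL 555 and 1696, and at the LOAEL 682 and 1644. Called changes were small, with medians between 0.36 and 0.40 log2 for these 6 groups. Flutamide had 3 called features at the ADI, 19 at the NOAEL and 7 at the LOAEL, where 3560, 3832 and 3923 features had an unadjusted p under 0.05 and 2457 are given by chance. Prochloraz counts did not rise with dose, and the LOAEL count fell to 389 without array 394 and rose to 1659 without array 393. The vinclozolin ADI count fell to 271 without control array 303, and without control array 301 it was 320 higher and 361 lower. Without array 372 the prochloraz ADI count was 914, without array 384 its NOAEL count was 851, and the vinclozolin NOAEL and LOAEL counts were 1332 and 1528 without arrays 321 and 334. The flutamide NOAEL count was 2 without array 351 or 353. With only the 2 groups in the fit the counts from the ADI to the LOAEL were 420, 516 and 0 for prochloraz, 0, 987 and 807 for vinclozolin, and 0 at each dose of flutamide.

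At PND30-40, flutamide at the LOAEL gave the most called features, 2299 higher and 1740 lower, with a median size of 0.48 log2. Flutamide had 418 higher and 213 lower at the ADI and 525 and 399 at the NOAEL, a total that fell to 173 without treated array 554. Prochloraz had 638 higher and 352 lower at the ADI, 62 and 62 at the NOAEL, and 30 and 5 at the LOAEL. These prochloraz counts gave no stable order of the doses: the ADI count was 130 without treated array 572, the NOAEL count was 489 without array 584 and 1 without control array 504, the LOAEL count was 2 without array 594, and with array weights the counts were 4120, 4481 and 4352. Vinclozolin had 0 called features at the ADI (limma; 4238 at an unadjusted p under 0.05, where chance gives 2322), 69 higher and 134 lower at the NOAEL, and 7 and 7 at the LOAEL. These counts depended on single arrays: without control array 501 the flutamide counts were 152, 231 and 2398 from the ADI to the LOAEL, the prochloraz ADI count was 394, and the vinclozolin ADI and LOAEL counts were 28 and 138. The vinclozolin NOAEL count was 36 without control array 504 and 455 without array 521, and its LOAEL count was 1 without array 532. Without treated array 564 the flutamide LOAEL count was 1969. With only the 2 groups in the fit the counts from the ADI to the LOAEL were 0, 3 and 2134 for flutamide, 1, 0 and 0 for prochloraz, and 0 at each dose of vinclozolin. Array weights raised the flutamide LOAEL count to 10063 and the vinclozolin ADI count to 1161.

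**Figure D1:**
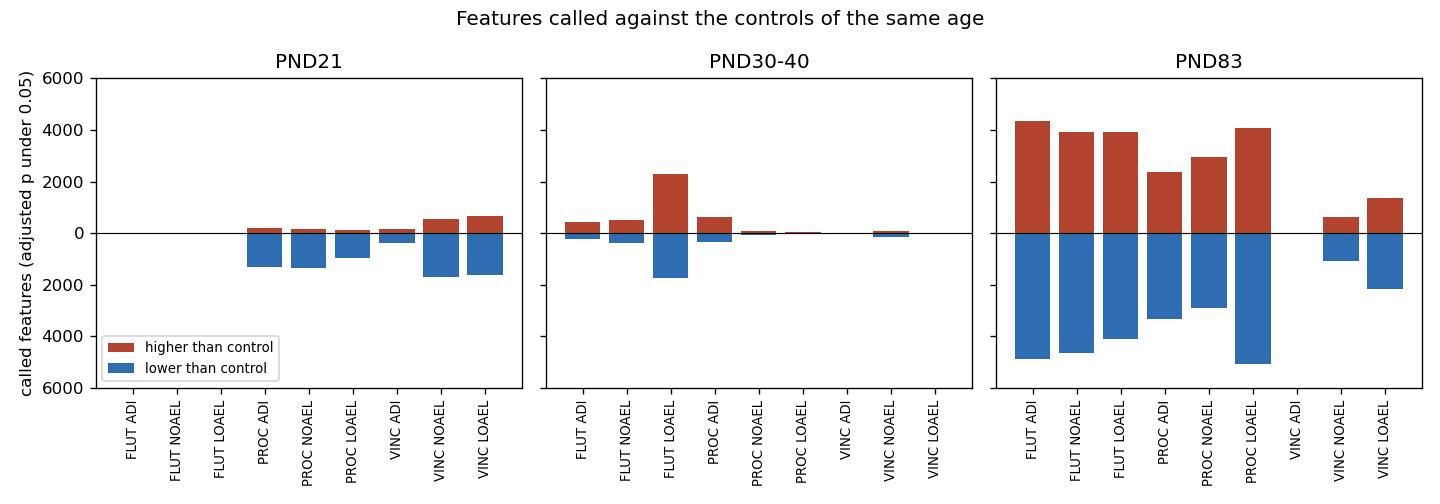
Bars give the number of array features called higher (up) or lower (down) than controls of the same age, for each compound and dose, with 4 animals per group. The largest total, 4338 higher and 4902 lower, was for flutamide at the ADI at PND83, against 2 and 1 at PND21. The most called lower were 5062, for prochloraz at the LOAEL at PND83.

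At PND83, flutamide and prochloraz differed from controls at between 5714 and 9240 features at every dose. Flutamide had 4338 higher and 4902 lower at the ADI, 3928 and 4643 at the NOAEL, and 3921 and 4117 at the LOAEL. Prochloraz had 2383 higher and 3331 lower at the ADI, 2936 and 2905 at the NOAEL, and 4091 and 5062 at the LOAEL. Vinclozolin had 0 called features at the ADI (limma; 3192 at an unadjusted p under 0.05, where chance gives 2301), 621 higher and 1071 lower at the NOAEL, and 1371 and 2161 at the LOAEL. Changes were small, with medians between 0.27 and 0.30 log2. Among features that changed at least 1.5-fold, flutamide had 485 higher and 407 lower at the ADI, 319 and 304 at the NOAEL, and 635 and 61 at the LOAEL. Prochloraz had 226 and 72, 216 and 64, and 479 and 132 from the ADI to the LOAEL, and vinclozolin had 38 and 36 at the NOAEL and 153 and 96 at the LOAEL. The flutamide count was higher at the ADI dose of 0.0025 mg/kg than at the LOAEL dose of 2.5 mg/kg. With the local mean removed on each array, the flutamide counts were 6918, 6705 and 8021 from the ADI to the LOAEL, so that order was reversed. The prochloraz ADI count was 3065 without control array 704 and 8666 without array 771, and its NOAEL count was 3344 without array 783. The vinclozolin NOAEL count was 619 without array 724, and its LOAEL count was 2128 without array 731. With only the 2 groups in the fit the counts from the ADI to the LOAEL were 6583, 5786 and 3771 for flutamide, 348, 2095 and 5222 for prochloraz, and 0, 30 and 961 for vinclozolin.

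The counts at PND83 followed the order of the sample numbers in part. With the 10 groups put in pairs of consecutive numbers, 8 arrays a pair, 953 features were called within the 5 pairs, and 1 of 945 possible pairings had as few. Flutamide at the LOAEL differed from prochloraz at the ADI, its partner by number, at 126 features, and from flutamide at the NOAEL at 4355. Some groups in different pairs also differed little: flutamide and prochloraz at the NOAEL at 146 features, flutamide at the ADI and prochloraz at the NOAEL at 302, and vinclozolin at the ADI and the NOAEL at 174. Prochloraz at the NOAEL and the LOAEL form a pair and differed at 645. Controls and vinclozolin at the ADI form a pair and differed at 0 features. Every other treated group lay outside the controls' pair, so a comparison with controls within a pair exists for vinclozolin at the ADI only. At PND21 and PND30-40, 196 and 75 of the 945 pairings had as few called features within pairs. Controls and vinclozolin at the ADI form a pair at these ages too, and differed at 546 and 0 features. At PND21 17 features were called between doses of the same compound over all 3 compounds, where an average way to put the groups in 3 sets of 3 gave 2980. At PND21 some groups of different compounds differed as little, with 0 features between prochloraz at the NOAEL and vinclozolin at the LOAEL, and 0 between flutamide at the NOAEL and prochloraz at the LOAEL.

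**Figure D2:**
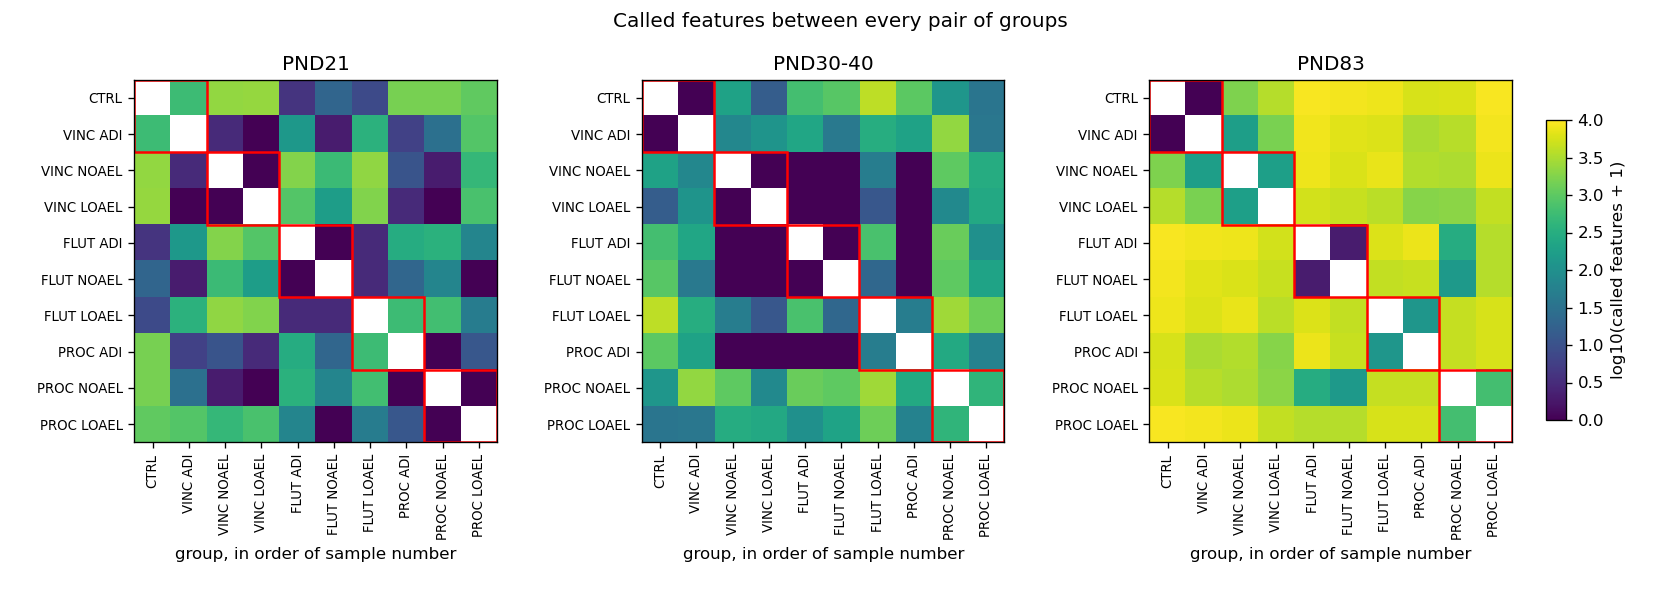
Colour gives log10 of the number of called features plus 1 between every pair of groups, at each age, with groups on both axes in order of sample number, and red boxes mark pairs of consecutive groups. At PND83 the 5 boxes hold 953 called features in all, and flutamide at the NOAEL and the LOAEL, which lie in different boxes, differ at 4355.

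Doses of flutamide and of prochloraz shared many called features at PND83. Of the flutamide features, 1554 were higher and 1273 lower at all 3 doses, and for prochloraz 743 and 849. For vinclozolin, with 0 called features at the ADI, these numbers were 0 and 0. The flutamide ADI and NOAEL, which form a pair by sample number, shared 2620 higher and 3364 lower features, where independent lists share 370.3 and 494.6. Lists drawn against the same controls are not independent, so those numbers are no measure of chance. Sharing was not particular to doses of a compound. Flutamide and prochloraz at the LOAEL shared 1775 higher and 1836 lower features, and flutamide at the ADI and the LOAEL 2005 and 1556. All groups of an age share their controls, so unchanged groups also correlate: log2 changes of flutamide at the ADI and the NOAEL correlated at r = 0.78 across features, where simulated unchanged groups gave 0.50, and at 0.51 on average with different controls, 2 each, for the 2 groups. Their covariance was 0.0405 against 0.00938 in unchanged groups. Flutamide at the ADI and the LOAEL, in different pairs, correlated at 0.596 against 0.501, and at 0.352 with split controls, and 117 features were called in opposite directions. For vinclozolin at the NOAEL and the LOAEL at PND21, r was 0.78 against 0.50 and 0.30 with split controls, with a covariance of 0.0309 against 0.00905. For prochloraz at the NOAEL and the LOAEL at PND30-40, r was 0.47 against 0.50, and -0.0013 with split controls, with a covariance of 0.0241 against 0.0171. Features are not independent replicates.

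The compounds were compared with each other at the LOAEL, at doses of 2.5, 30 and 20 mg/kg per day that differ. Flutamide and prochloraz differed at 46 features at PND21, 1322 at PND30-40 and 5713 at PND83. Flutamide and vinclozolin differed at 1736, 11 and 3846 features, and prochloraz and vinclozolin at 714, 258 and 4221. At PND83 these groups all lay in different pairs of sample numbers. Many of these counts depended on single arrays. At PND21 the count of 46 was 3 without flutamide array 361 and 387 without prochloraz array 393, the count of 1736 was 844 without array 361, and the count of 714 was 175 without vinclozolin array 332 and 2211 without array 393. At PND30-40 the count of 11 was 0 without flutamide array 562 and 935 without vinclozolin array 533, and without prochloraz array 594 the counts of 1322 and 258 were 391 and 49. At PND83 the counts were 3571 without array 763, 2445 without array 734 and 2789 without array 794. With only the 2 groups in the fit, flutamide and prochloraz differed at 0, 2386 and 1565 features from PND21 to PND83, flutamide and vinclozolin at 458, 8 and 1366, and prochloraz and vinclozolin at 0, 0 and 1909. Log2 changes of flutamide and prochloraz at the LOAEL at PND83 correlated at 0.62 across features, against 0.51 for unchanged groups and 0.37 with split controls, with a covariance of 0.0326 against 0.00952.

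The response at the LOAEL differed between ages at 6801 features for flutamide, 4380 for prochloraz and 1825 for vinclozolin (limma, moderated F test of 2 interaction contrasts). This fit shares 1 spread per feature over all ages, and the PND21 arrays had been normalised separately. The counts can therefore also hold differences in spread or normalisation between ages. The vinclozolin count rose to 3364 without control array 501. Across features, log2 changes of the same compound and dose at different ages correlated weakly, and in some groups inversely. The mean over the 9 groups was 0.026 between PND21 and PND30-40 (-0.0108 to 0.0800), -0.030 between PND21 and PND83 (-0.145 to 0.0487), and -0.079 between PND30-40 and PND83. The last ran from -0.2095 for flutamide at the LOAEL to 0.0387, with -0.159 for prochloraz at the ADI. Between different groups the means were 0.015, -0.053 and -0.079, with ranges of -0.1061 to 0.1081, -0.1989 to 0.0842 and -0.3085 to 0.1455. The inverse correlations of single groups thus lay within the range of different groups. All groups of an age also share their controls, so an inverse value is no mark of that group's response. A one-sided test of 100000 label permutations asked whether same-group correlations lay above the others. The adjusted p in this family of 3 tests was 0.202 between PND21 and PND30-40, 0.0227 between PND21 and PND83, and 0.533 between PND30-40 and PND83.

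Features that rose with late maturation were lower at PND83 in animals given flutamide at the 2 lower doses, which form a pair by sample number. Of 569 such features, 414 were called lower and 9 higher at the ADI, with a mean of -0.484 log2 against 0.0062 in all others, and 389 were lower and 7 higher at the NOAEL, with a mean of -0.425. At the LOAEL 87 were lower and 25 higher, with a mean of -0.085. By camera the adjusted p was 7.15e-61 at the ADI and 5.32e-54 at the NOAEL, and with an estimated correlation the adjusted p was 0.0095 and 0.00979. At the LOAEL it was 0.00173, and 0.918 with an estimated correlation. For prochloraz at the NOAEL, 131 of 424 were lower and 13 higher, with a mean of -0.229 (adjusted p = 3.15e-18, and 0.327 with an estimated correlation), and at the LOAEL the mean was -0.131 (adjusted p = 0.000578, and 0.905). For prochloraz at the ADI the mean was -0.0718, with an adjusted p of 0.0755, which was 0.0283 with no filter and 0.935 with an estimated correlation. Flutamide at the ADI and the NOAEL differed from each other at 1 feature, and from prochloraz at the NOAEL, with the next largest fall, at 302 and 146. The falls can therefore not be told apart from handling by sample number. Features that fell with late maturation had in vinclozolin a mean of -0.083 at the NOAEL and -0.143 at the LOAEL (adjusted p = 0.00334 and 0.000175, and 0.7 and 0.538 with an estimated correlation). For flutamide their mean was 0.00783, 0.00667 and 0.0208 from the ADI to the LOAEL (camera, adjusted p = 0.574, 0.457 and 0.378). No prochloraz dose passed either (adjusted p = 0.317, 0.746 and 0.121). At PND21, features that rose from PND21 to PND30-40 had a mean of -0.0525 for flutamide at the ADI, 0.0849 for prochloraz at the LOAEL and 0.0502 for vinclozolin at the NOAEL, and features that fell had 0.0292, -0.0645 and -0.048. Adjusted p (camera) for these 6 means was up to 0.00972, and at least 0.652 with an estimated correlation. Of 8048 features that rose, 47 were called higher and 68 lower for prochloraz at the LOAEL. Of 7988, 75 and 114 were for vinclozolin at the NOAEL. Features that fell had 2 higher and 426 lower, and 104 and 938, in the same 2 groups. Calls lower also outnumbered calls higher over all 49134 features, with 106 higher and 949 lower, and 555 and 1696. The counts among features that rose therefore do not go against their positive means. Over all 54 such tests 25 passed with the preset correlation and 2 with an estimated one.

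At PND30-40, no maturation feature group passed with an estimated correlation. Features that fell with late maturation had a mean of -0.378 log2 for flutamide at the LOAEL, where 33 of 149 were called lower and 0 higher (camera, adjusted p = 2.47e-11, and 0.327 with an estimated correlation). Features that fell were drawn for each compound from the other 2, and numbered 149 for flutamide, 112 for prochloraz and 138 for vinclozolin. Their mean was under 0 in 7 of the other 8 treated groups, all compared with the same 4 controls. In these 7 it lay between -0.222 and -0.123, with adjusted p (camera) up to 0.00043, and from 0.64 to 0.889 with an estimated correlation. Of 149 members, 8 and 13 were called lower for flutamide at the ADI and the NOAEL. Of 112, 10 were called lower for prochloraz at the ADI, and of 138, 4 for vinclozolin at the NOAEL, with 0 in the other 3 groups. For prochloraz at the NOAEL the mean was 0.0815 (adjusted p = 0.221). Features that rose had 67 called higher and 10 lower among 561 for flutamide at the LOAEL, with a mean of 0.121 and an adjusted p of 0.0566, which was 0.0208 with no filter and 0.935 with an estimated correlation. Their mean was -0.0977 and -0.0677 for flutamide at the ADI and the NOAEL (adjusted p = 0.0126 and 0.0595, and 0.935 for both with an estimated correlation). For prochloraz, with 416 such features, the mean was -0.14, -0.0946 and -0.142 from the ADI to the LOAEL, with adjusted p up to 0.00106, and at least 0.905 with an estimated correlation. The maturation index was 0.931 ± 0.0264 (SD, n = 4) in flutamide at the LOAEL and 0.896 ± 0.0238 in controls, a difference of 0.0357 with an exact two-sided permutation p of 0.114 and an adjusted p of 0.513 over 9 comparisons. None of the 9 treated groups passed, and 0.0286 is the smallest p that 4 against 4 animals allow. The exact age of each animal in the range is not given in the sources used here.

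**Figure D3:**
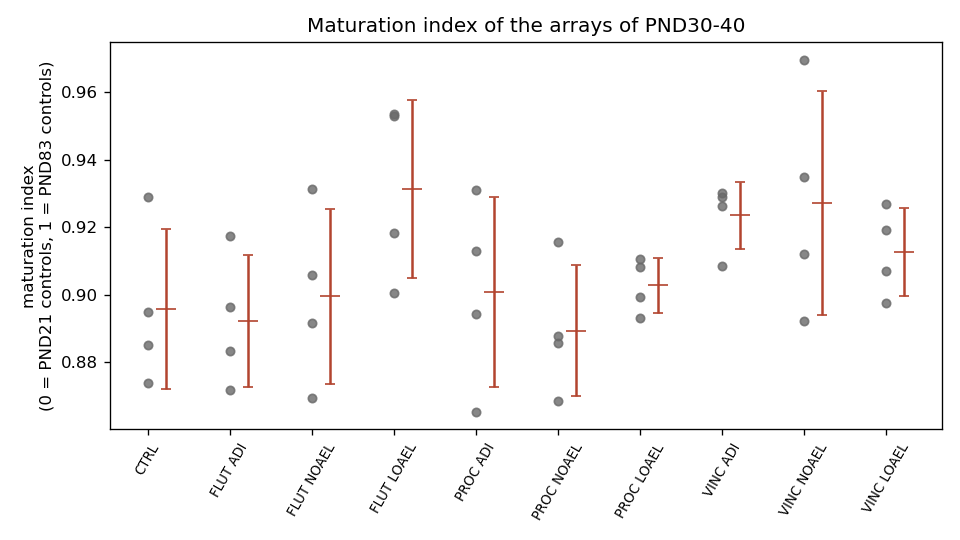
Points give the maturation index of each array of PND30-40, on a scale where 0 is the mean of PND21 controls and 1 that of PND83 controls, and red bars give the group mean and SD of 4 animals. Flutamide at the LOAEL averaged 0.931 and controls 0.896, and the arrays of the 2 groups overlap through control array 501 only.

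Among the 9 LOAEL comparisons, the 2 largest rises were both in vinclozolin at PND83. Feature 30607 was 10.57 ± 0.091 log2 (SD, n = 4) against 6.94 ± 0.164 in controls, a rise of 3.63 log2 (SE 1.07, limma adjusted p = 0.0317), and feature 23512 was 10.53 ± 0.0894 against 7.01 ± 0.139, a rise of 3.52 (SE 1.07, adjusted p = 0.0386). Over all arrays of that age feature 30607 ran from 6.62 to 10.7, so that other groups held both levels. The 2 largest falls were in flutamide at PND30-40, where feature 17241 was 5.83 ± 0.401 against 8.73 ± 1.92 (limma adjusted p = 0.0122) and feature 3456 was 7.11 ± 0.113 against 9.69 ± 1.08 (adjusted p = 0.0463). For feature 17241 the groups overlapped, with a highest treated array of 6.43 and a lowest control of 6.05. Its treated mean lay under the 30th percentile of an array, near 6.39. Feature 3456 was also called 3.47 log2 higher in vinclozolin at the LOAEL at PND83 (limma adjusted p = 0.0365), a rise near those of features 30607 and 23512. The named features are therefore not shown to be separate responses. The calls of features 30607 and 23512 ended with any 1 of the 8 arrays left out, with adjusted p-values up to 0.0694 and 0.081, and over all settings these ran from 2.24e-07 and 1.47e-07. For feature 17241 the limma adjusted p was 0.0537 without control array 504 and ran from 6.08e-05 to 0.0735 over all settings. For feature 3456 it was 0.135 without control array 501, the highest, and 0.0206 at the lowest.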

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

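The tests of the sample-number order, of doses of a compound, of the array surface and with the maturation index were chosen only after the result was seen.

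The responses at the LOAEL differed between ages by the moderated F test at 6801 features for flutamide, 4380 for prochloraz and 1825 for vinclozolin. Chance in grouping could not be excluded for vinclozolin, where 15 of 100 splits, the real one among them, gave as many features, up to 5762. Feature 3456 was among them for flutamide, with an adjusted p of 0.0362. In feature 17241, 1 array of flutamide at the LOAEL at PND30-40 stood at 6.433 log2, far above the other 3. Of 18 groups of 4 examined in this way 1 stood out, where chance gives 0.9.

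Differences from control at PND83 reached 9240 features, for flutamide at its lowest dose, with no rise by dose in flutamide in the main fit. With the local mean of each array taken off, its counts were 6918, 6705 and 8021 from the ADI to the LOAEL. A smooth trend over the array surface is argued against as the whole cause, since 68.7% of called features of the 9 comparisons together stayed called with the local mean taken off. For prochloraz at the NOAEL alone 2820 of 5841 did, so for that group it is not excluded, and for vinclozolin at the NOAEL 963 of 1692. Handling of arrays in sets of 8 by sample number may account for them: a share of 0.00106 of the pairings had as few called features within pairs. The order of numbers does not account for every count, since flutamide and prochloraz at the NOAEL, in different sets, differed at 146 features. For an effect shared by the doses of a compound, the share was 0.0393 of the ways to form 3 sets of 3, which met the prediction. Doses of a compound have neighbouring numbers, so this test cannot tell such an effect from the order of numbers. Flutamide at the LOAEL differed from its ADI and NOAEL at 6233 and 4355 features, and prochloraz at the ADI from its NOAEL and LOAEL at 4493 and 5790. Flutamide at the ADI and the NOAEL differed at 1, prochloraz at the NOAEL and the LOAEL at 645, and vinclozolin doses at 174, 1582 and 181. Slides or handling days are not given in the sources used here, so handling and treatment stay open for all groups but vinclozolin at the ADI.

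Flutamide at the LOAEL at PND30-40 differed from controls at 4039 features. With the maturation index as a covariate 3175 of them stayed called, in a fit that called 8142 in all. The loss predicted if more mature testes were the whole cause was therefore not seen. But the index cannot decide this, since it runs from PND21 to PND83 and arrays of PND30-40 already averaged 0.9075 on it. Features that fell with late maturation had 33 called lower and 0 higher, and those that rose 67 higher and 10 lower. More mature testes stay open as a cause. Control array 501 may carry part of the 4039, since 2398 features were called without it. Without treated array 564 there were 1969, so the loss is not particular to that control. Handling in sets of 8 was left undecided, with a share of 0.0794 of pairings. Of 460 features called within pairs, 412 were between prochloraz at the NOAEL and the LOAEL. Vinclozolin at the ADI, with 0 called features, was the partner of the controls by number. A treatment effect stays open.

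Prochloraz and vinclozolin differed from controls at PND21 while flutamide had few called features. Chance in grouping could not be excluded for vinclozolin at the ADI, with 546 features against 1061 in another split, or for prochloraz at the LOAEL, with 1055 against 1570. Control array 303 is argued against as the whole cause, since the 6 counts summed to 6519 without it and 9172 with it, a margin close to the bound of a 1.5-fold loss. Sets of 8 gave a share of 0.207 and left that handling undecided. Few features differed between doses of a compound (a share of 0.00357, the smallest that 280 ways allow), which is consistent with a compound effect, or with handling compound by compound, since the 12 arrays of a compound have consecutive numbers. It is not particular to a compound, since some groups of different compounds differed as little, with 0 features between prochloraz at the NOAEL and vinclozolin at the LOAEL and 1 between both compounds at the NOAEL.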

How the results depend on the processing

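Tests with the array surface, the maturation index, doubted arrays and maturation feature groups were chosen only after the result was seen. Centring each array on its 75th percentile moved none of the 41 counts by over 1.5 times, but quantile-normalised values share that percentile, so this says nothing about stability. Most counts depended on the spread being shared by all groups of an age: 30 of 38 fell by over 1.5 times with 8 arrays in the fit, which have fewer degrees of freedom. For the other settings the cause was not tested. The mean of all probes of a gene, the gene list tests, sentinel genes, normexp and slide as a block were not run, and the replicate block was not run at PND83, where vinclozolin at the ADI carries other digits. Arrays with the same last digit deviated together with a mean correlation of 0.0857 at PND21 and 0.132 at PND30-40, against -0.0287 and -0.0433 for other digits. Group means were removed, so the value for other digits follows from that for the same digit and is no separate contrast. Of 180 pairs with the same digit, 82 and 102 had a correlation over 0.1, and the lowest were -0.273 and -0.325. At PND83 the mean was 0.0124, with 9 of 162 pairs over 0.1. With the digit as a block 17 of 24 counts rose by over 1.5 times and 0 fell. The main fit holds no block, and whether the digit pairs the arrays stays open. Of the maturation feature groups, prochloraz at the ADI at PND21 changed its direction against other features with no filter (mean 0.00238 log2, adjusted p = 0.996, for features that fall with age). Signal over background is not given in the sources used here and could not be assessed.

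With no filter, 36 of 41 counts stayed within 1.5 times, 4 rose and 1 fell, with moved counts at PND21 FLUT NOAEL 12, and at PND30-40 PROC NOAEL 292, PROC LOAEL 183, VINC LOAEL 23, and at PND83 VINC ADI 10.

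With the 50th percentile filter, 36 of 41 counts stayed within 1.5 times, 1 rose and 4 fell, with moved counts at PND21 FLUT LOAEL 2, PROC LOAEL 628, and at PND30-40 PROC LOAEL 4, VINC ADI 2, FLUT LOAEL against VINC LOAEL 5.

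With only the 2 groups compared in the fit, 7 of 38 counts stayed within 1.5 times, 1 rose and 30 fell, with moved counts at PND21 FLUT ADI 0, FLUT NOAEL 0, FLUT LOAEL 0, PROC ADI 420, PROC NOAEL 516, PROC LOAEL 0, VINC ADI 0, VINC NOAEL 987, VINC LOAEL 807, FLUT LOAEL against PROC LOAEL 0, FLUT LOAEL against VINC LOAEL 458, PROC LOAEL against VINC LOAEL 0, and at PND30-40 FLUT ADI 0, FLUT NOAEL 3, FLUT LOAEL 2134, PROC ADI 1, PROC NOAEL 0, PROC LOAEL 0, VINC NOAEL 0, VINC LOAEL 0, FLUT LOAEL against PROC LOAEL 2386, PROC LOAEL against VINC LOAEL 0, and at PND83 FLUT LOAEL 3771, PROC ADI 348, PROC NOAEL 2095, PROC LOAEL 5222, VINC NOAEL 30, VINC LOAEL 961, FLUT LOAEL against PROC LOAEL 1565, FLUT LOAEL against VINC LOAEL 1366, PROC LOAEL against VINC LOAEL 1909.

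With array weights, 19 of 41 counts stayed within 1.5 times, 18 rose and 4 fell, with moved counts at PND21 FLUT ADI 13, FLUT NOAEL 43, PROC LOAEL 627, VINC ADI 203, FLUT LOAEL against PROC LOAEL 16, PROC LOAEL against VINC LOAEL 399, and at PND30-40 FLUT ADI 3948, FLUT NOAEL 4901, FLUT LOAEL 10063, PROC ADI 4120, PROC NOAEL 4481, PROC LOAEL 4352, VINC ADI 1161, VINC NOAEL 1681, VINC LOAEL 1165, FLUT LOAEL against PROC LOAEL 6247, FLUT LOAEL against VINC LOAEL 3007, PROC LOAEL against VINC LOAEL 2555, and across ages CTRL PND83 against PND30-40 23955, FLUT LOAEL by age 11112, PROC LOAEL by age 8110, VINC LOAEL by age 5304.

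With the last digit of the sample number as a replicate block, 7 of 24 counts stayed within 1.5 times, 17 rose and 0 fell, with moved counts at PND21 FLUT ADI 7, FLUT NOAEL 39, FLUT LOAEL 11, FLUT LOAEL against PROC LOAEL 194, PROC LOAEL against VINC LOAEL 1099, and at PND30-40 FLUT ADI 2122, FLUT NOAEL 2875, FLUT LOAEL 6266, PROC ADI 3152, PROC NOAEL 760, PROC LOAEL 932, VINC ADI 33, VINC NOAEL 680, VINC LOAEL 92, FLUT LOAEL against PROC LOAEL 2544, FLUT LOAEL against VINC LOAEL 63, PROC LOAEL against VINC LOAEL 1287.

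With the trend across the array removed, 29 of 39 counts stayed within 1.5 times, 8 rose and 2 fell, with moved counts at PND30-40 FLUT ADI 1112, FLUT NOAEL 1541, PROC LOAEL 325, VINC ADI 17, VINC NOAEL 378, VINC LOAEL 47, PROC LOAEL against VINC LOAEL 591, and at PND83 PROC NOAEL 3258, PROC LOAEL against VINC LOAEL 2137, and at PND21 FLUT LOAEL against PROC LOAEL 84.

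With doubted arrays left out (303, 313 and 392 at PND21, 501, 521, 531 and 581 at PND30-40), 11 of 24 counts stayed within 1.5 times, 5 rose and 8 fell, with moved counts at PND21 FLUT NOAEL 6, PROC LOAEL 426, VINC ADI 210, FLUT LOAEL against PROC LOAEL 20, PROC LOAEL against VINC LOAEL 315, and at PND30-40 FLUT ADI 322, FLUT NOAEL 513, PROC LOAEL 56, VINC ADI 33, VINC NOAEL 312, VINC LOAEL 70, FLUT LOAEL against PROC LOAEL 2381, FLUT LOAEL against VINC LOAEL 2.

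With a 1.5-fold minimum, 6 of 41 counts stayed within 1.5 times, 0 rose and 35 fell, with moved counts at PND21 FLUT NOAEL 4, PROC ADI 264, PROC NOAEL 269, PROC LOAEL 76, VINC ADI 67, VINC NOAEL 350, VINC LOAEL 399, FLUT LOAEL against PROC LOAEL 4, FLUT LOAEL against VINC LOAEL 231, PROC LOAEL against VINC LOAEL 72, and at PND30-40 FLUT ADI 244, FLUT NOAEL 362, FLUT LOAEL 1254, PROC ADI 303, PROC NOAEL 36, PROC LOAEL 18, VINC NOAEL 82, VINC LOAEL 8, FLUT LOAEL against PROC LOAEL 477, PROC LOAEL against VINC LOAEL 88, and at PND83 FLUT ADI 892, FLUT NOAEL 623, FLUT LOAEL 696, PROC ADI 298, PROC NOAEL 280, PROC LOAEL 611, VINC NOAEL 74, VINC LOAEL 249, FLUT LOAEL against PROC LOAEL 292, FLUT LOAEL against VINC LOAEL 321, PROC LOAEL against VINC LOAEL 173, and across ages CTRL PND83 against PND30-40 5650, FLUT LOAEL by age 2850, PROC LOAEL by age 1976, VINC LOAEL by age 1071.

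With the maturation index as a covariate, 0 of 12 counts stayed within 1.5 times, 11 rose and 1 fell, with moved counts at PND30-40 FLUT ADI 1201, FLUT NOAEL 2292, FLUT LOAEL 8142, PROC ADI 2156, PROC NOAEL 395, PROC LOAEL 177, VINC ADI 1, VINC NOAEL 81, VINC LOAEL 30, FLUT LOAEL against PROC LOAEL 3711, FLUT LOAEL against VINC LOAEL 242, PROC LOAEL against VINC LOAEL 551.

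Leaving out single arrays moved these counts by over 1.5 times, given as lowest to highest with the array left out. For PND21, FLUT ADI 2 (342) to 13 (341), FLUT NOAEL 2 (351) to 30 (352), FLUT LOAEL 4 (303) to 16 (362), PROC ADI 914 (372) to 1610 (301), PROC NOAEL 851 (384) to 1677 (304), PROC LOAEL 389 (394) to 1659 (393), VINC ADI 271 (303) to 732 (311), VINC NOAEL 1332 (321) to 2517 (304), VINC LOAEL 1528 (334) to 2369 (301), FLUT LOAEL against PROC LOAEL 3 (361) to 387 (393), FLUT LOAEL against VINC LOAEL 844 (361) to 1651 (363), PROC LOAEL against VINC LOAEL 175 (332) to 2211 (393). For PND30-40, FLUT ADI 152 (501) to 662 (541), FLUT NOAEL 173 (554) to 966 (502), FLUT LOAEL 1969 (564) to 3365 (502), PROC ADI 130 (572) to 1114 (571), PROC NOAEL 1 (504) to 489 (584), PROC LOAEL 2 (594) to 53 (501), VINC ADI 0 (504) to 28 (501), VINC NOAEL 36 (504) to 455 (521), VINC LOAEL 1 (532) to 138 (501), FLUT LOAEL against PROC LOAEL 391 (594) to 943 (561), FLUT LOAEL against VINC LOAEL 0 (562) to 935 (533), PROC LOAEL against VINC LOAEL 49 (594) to 317 (533). For PND83, PROC ADI 3065 (704) to 8666 (771), PROC NOAEL 3344 (783) to 5128 (784), VINC ADI 0 (702) to 2 (704), VINC NOAEL 619 (724) to 1857 (723), VINC LOAEL 2128 (731) to 3005 (733), FLUT LOAEL against PROC LOAEL 3571 (763) to 5447 (762), FLUT LOAEL against VINC LOAEL 2445 (734) to 3534 (761), PROC LOAEL against VINC LOAEL 2789 (794) to 3504 (791). For the responses by age, VINC LOAEL by age 1305 (303) to 3364 (501).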

Other observations

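The test of features with 2 levels at PND83 was chosen only after the count of such features was seen. Some features sat at 2 separate levels among the 40 arrays of an age, with a gap of at least 1.5 log2 and at least 5 arrays on either side. There were 4 at PND21, 6 at PND30-40 and 57 at PND83, and the last included 3 of the 4 named features. It was first supposed that the same features would have 2 levels at every age, but 0 of 43203 did. That hypothesis failed, and its test of correlation had no features to run on. The ratio to the number that independent lists give was 0. That number was 6.3e-07, so a ratio of 0 was near certain by chance and says nothing. The 57 features at PND83 were then examined alone. They could follow 1 common factor of the arrays, but the median absolute correlation between them was 0.147, against 0.143 for random features, which argues against it. Of their 1596 pairs, 104 had an absolute correlation over 0.9, so small sets of them moved together.

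For every comparison the 8 arrays were split in all 35 ways into 4 and 4. For the responses by age 100 splits were counted, the real one among them and the others drawn at random. The smallest share that 35 splits allow is 0.0286, and each comparison is read alone, with no allowance for the number of comparisons. At PND21, the real split gave the most called features, so that chance in grouping can be excluded at that share (1 of 35 splits), for these, each with the real count against the highest of the others: FLUT NOAEL 19 against 0, FLUT LOAEL 7 against 0, PROC ADI 1489 against 23, PROC NOAEL 1505 against 16, VINC NOAEL 2251 against 34, VINC LOAEL 2326 against 36, FLUT LOAEL against VINC LOAEL 1736 against 1, PROC LOAEL against VINC LOAEL 714 against 4. The FLUT NOAEL count was 2 without array 351 or 353, and 0 with only the 2 groups in the fit, so the exclusion does not make it a stable count. Chance could not be excluded for FLUT ADI 3 against 8 (3 of 35), PROC LOAEL 1055 against 1570 (2 of 35), VINC ADI 546 against 1061 (2 of 35), FLUT LOAEL against PROC LOAEL 46 against 2013 (2 of 35).

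At PND30-40, the real split gave the most called features, so that chance in grouping can be excluded at that share (1 of 35 splits), for these, each with the real count against the highest of the others: FLUT ADI 631 against 4, FLUT NOAEL 924 against 0, FLUT LOAEL 4039 against 78, PROC ADI 990 against 1, PROC LOAEL 35 against 1, FLUT LOAEL against PROC LOAEL 1322 against 5, PROC LOAEL against VINC LOAEL 258 against 3. Chance could not be excluded for PROC NOAEL 124 against 1682 (5 of 35), VINC NOAEL 203 against 4188 (2 of 35), VINC LOAEL 14 against 5731 (6 of 35), FLUT LOAEL against VINC LOAEL 11 against 389 (2 of 35). The real count of VINC ADI was 0, which every split reaches (35 of 35, with a highest of 17), so the splits say nothing about chance there.

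At PND83, the real split gave the most called features, so that chance in grouping can be excluded at that share (1 of 35 splits), for these, each with the real count against the highest of the others: FLUT ADI 9240 against 38, FLUT NOAEL 8571 against 8, FLUT LOAEL 8038 against 154, PROC ADI 5714 against 3743, PROC NOAEL 5841 against 2, PROC LOAEL 9153 against 166, VINC NOAEL 1692 against 122, VINC LOAEL 3532 against 5, FLUT LOAEL against PROC LOAEL 5713 against 354, FLUT LOAEL against VINC LOAEL 3846 against 8, PROC LOAEL against VINC LOAEL 4221 against 3. The real count of VINC ADI was 0, which every split reaches (35 of 35, with a highest of 62), so the splits say nothing about chance there. At every age, excluding chance in grouping does not separate treatment from handling by sample number or from differences between litters, which could give the same counts.

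Of the comparisons across ages, CTRL PND30-40 against PND21 gave 39004 against 0 (1 of 35 splits), CTRL PND83 against PND30-40 gave 15550 against 8 (1 of 35 splits), FLUT LOAEL by age gave 6801 against 3126 (1 of 100 splits), PROC LOAEL by age gave 4380 against 1452 (1 of 100 splits), VINC LOAEL by age gave 1825 against 5762 (15 of 100 splits). Chance can be excluded for all of these but VINC LOAEL by age. At PND30-40, other splits gave up to 1682 features for prochloraz at the NOAEL, 4188 for vinclozolin at the NOAEL and 5731 for vinclozolin at the LOAEL, many times the real counts, which points to a structure of these arrays other than treatment. In these highest splits control array 501 stood with treated arrays 581, 582 and 583, with 521, 522 and 523, and with 531, 534 and control array 502. Array 501 had the lowest array weight of that age, 0.206.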
